A study of Caenorhabditis elegans with 4 samples.

How the data were processed

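Chromatin of early embryos was crosslinked with formaldehyde, sheared by sonication and precipitated with the 8WG16 antibody, per the labels' protocols. Libraries were made from the precipitated DNA of 2 samples and from input DNA of 2 samples. The labels give different sonication and library protocols for the input and the precipitated samples. Reads were aligned with BWA to build ce10, per the submitters' processing notes, and the file headers give the build as WormBase WS220. The BWA version and settings, read numbers, read filters and the treatment of reads that map to several places are not given in the sources used here.

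The authors deposited one peak list for each of the 2 precipitated samples, called per sample with a program named MACS in the lists (version not given in the sources used here), and one list for the whole series, called with MACS v2, per the file headers and the caller named on each line. Which input served as control, and how the replicates were brought together for the series-wide list, are not given in the sources used here. Each line of a list gives the first and last base of a peak (1-based) and a score. The score values are those of the authors' peak caller and were used as deposited, only to rank or filter peaks within a list or to describe a peak. Between the replicates only their correlation was taken. Their scale is not stated. In the replicate lists many peaks share a score of 3100 and few lie above it. In the series-wide list they run from 1.31 to 213, so scores were not compared in size between that list and the others.

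Lists were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. All listed peaks on the 6 nuclear chromosomes were kept, and the 13 peaks on the mitochondrial genome in the series-wide list were set aside. The length of each chromosome was taken as the last listed peak end over all lists, 100.3 Mb in all. A peak counted as found in another list when it overlapped a peak of it by at least 1 bp. Chance overlap was measured with 1000 random circular shifts of the other list within each chromosome. For scores, each replicate 1 peak was paired with the highest-scoring replicate 2 peak that it overlapped, and 95% intervals came from 1000 bootstrap samples of peaks. Density comparisons used the replicate 1 peaks that overlapped a replicate 2 peak, placed by their midpoints. X and autosomes were compared by 100000 permutations of the labels of 1 Mb bins. Centres and outer parts were compared by an exact sign-flip test over the 6 chromosomes. Neighbouring bins are alike, so p-values over bins are too small, and no test across samples was made with 2 replicates of a single group.

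Regions were named by a rule fixed before the data were examined: the 10 shared peaks with the highest mean percentile of score in the 2 replicate lists, the 3 highest of each chromosome, and the 5 highest peaks of each replicate without a counterpart. Ties were ordered by position. The tests were tried on simulated lists. None of 20 pairs of independently placed lists of the real sizes (4343 peaks in the first) was called as overlapping. With 4510 simulated peaks, the X test called all 20 simulations in which X was thinned to 0.6 of its peaks. The mean recovered ratio was 0.602. The test called 0 of 20 simulations without a difference, but there the peak number of each chromosome was set in proportion to its length. That outcome was therefore fixed in advance and does not measure how often the test calls falsely. Simulated peaks were also placed at random within chromosomes, without the clustering seen in the real lists. A centre made 2 times as dense came out at 2.02 times.

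Each comparison was also made with other settings, chosen before the data were examined: a stricter overlap, the stronger part of each list by score, equal list sizes, merging of peaks less than 200 bp apart, bins of 500 kb, covered bases in place of peaks, a narrower centre, and each list alone. Gene-based comparisons (peaks at gene 5′ ends, peaks along genes, and gene lists) were not run, since the gene table at hand is of build WBcel235 and mixing builds would misplace features. The depth of the libraries is unknown, so no statement on depth is made. Intervals on shares of peaks are exact (Clopper-Pearson) and cover counting error only.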

Results

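RNA polymerase II occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in early embryos of wild-type Caenorhabditis elegans N2, the Bristol laboratory strain. The worms were kept at 20 °C and the population held males and hermaphrodites. The antibody, 8WG16, is a mouse monoclonal that binds mainly the unphosphorylated C-terminal domain of the largest polymerase subunit, the form of the enzyme that is recruited to promoters. The question put by this design is where along the genome this form of the polymerase lies in the early embryo. The series holds 4 samples, 2 immunoprecipitated (replicates 1 and 2) and 2 of input DNA. Peak lists of the 2 immunoprecipitated samples and one list for the whole series were analysed, and the input samples were not analysed here as samples of their own. The labels do not say whether the replicates came from separate embryo preparations. Sequencing depth is unknown, because the lists carry positions and scores but no read counts. All positions are in the WormBase WS220 build. Genes are not named, because the gene table at hand is of another build (WBcel235) and positions were not carried between builds.

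RNA polymerase II peaks covered a sizeable part of every nuclear chromosome in both replicates. Replicate 1 listed 4343 peaks that covered 14.0 Mb, or 14.0% of the genome, and replicate 2 listed 5585 peaks that covered 19.1 Mb, or 19%. The peaks were domains of a few kilobases: the median width was 2186 bp in replicate 1 (interquartile range 1385 to 3920 bp) and 2149 bp in replicate 2 (1373 to 4109 bp). Domains wider than 10 kb numbered 161 in replicate 1 (3.71% of its peaks) and 285 in replicate 2 (5.10%). The broadest domain found in both lay on chromosome III, from 12595169 to 12624855 in replicate 1 (29687 bp) and from 12595141 to 12628886 in replicate 2 (33746 bp). The next broadest in replicate 1 lay on chromosome II from 11613312 to 11638510 (25199 bp), and the third on chromosome I from 11074579 to 11097696 (23118 bp). These 3 domains were chosen for their width after the values were seen. The chromosome III domain scored 252 in replicate 1 and 520 in replicate 2, against medians of 226 and 568 over all peaks. The chromosome II domain scored 152 and 3100, and the chromosome I domain 1603 and 2383. The rank of these domains differed in the series-wide list, whose scores were compared only within it. Its highest-scoring peak in each domain scored 133.73 on III, 129.89 on II and 84.76 on I. The median over the nuclear peaks of that list was 6.15 and the maximum 212.56.

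**Figure D1:**
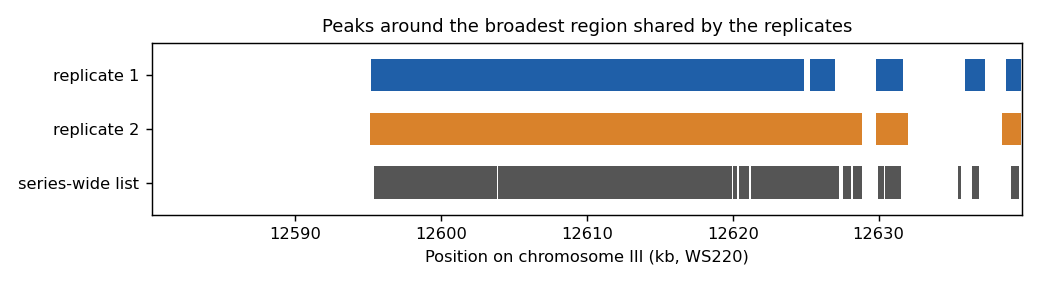
Map of the broadest region shared by the replicates, on chromosome III (x axis, position in kb, WS220), with 15 kb on either side of the replicate 1 peak. Each box is a peak of replicate 1, replicate 2 or the series-wide list: the replicate 1 peak of 29687 bp is met by 6 peaks of the series-wide list, the widest of 16054 bp.

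The 10 shared regions ranked highest lay on chromosomes I to IV, in an order set by the few scores above 3100, a value that many peaks of every chromosome share. Ranked by the mean percentile of the score in the 2 lists, the first region was on chromosome II from 13319478 to 13328418 in replicate 1 and from 13319817 to 13331418 in replicate 2, with scores of 3100 and 3195. The second was on chromosome III from 4193085 to 4197461 in replicate 1, with scores of 1800 in replicate 1 and 3230 in replicate 2. Chromosome III held another 2 of the 10 highest, from 10469944 to 10477111 (scores 3227 and 3100) and from 9611153 to 9616948 (scores 1454 and 3219). Chromosome IV held 3, from 15940602 to 15948199, from 8771857 to 8781301 and from 558806 to 569398, which scored 3186, 3149 and 3141 in replicate 1 and 3100 each in replicate 2. Chromosome I held 2, from 13628248 to 13634360 (scores 1740 and 3137) and from 8133184 to 8136708 (scores 3121 and 3100). Chromosome II held another, from 8216062 to 8225882, with scores of 3228 and 3100. The third region of chromosome I ran from 377138 to 383472 and that of chromosome II from 215660 to 222835, each at 3100 in both replicates.

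On chromosomes V and X, the top regions were tied at 3100 in both replicates and are given in order of position. Those of V ran from 352728 to 360829, from 1470995 to 1479176 and from 1568418 to 1586947 in replicate 1. Those of X ran from 1439150 to 1447421, from 1845577 to 1856976 and from 2037862 to 2047043. Many peaks shared this value: 186 peaks of replicate 1 and 1103 of replicate 2 scored exactly 3100, and only 6 and 29 scored higher, so the order of the strongest peaks is poorly resolved. Among regions shared by the replicates, 185 of 3852 scored 3100 or more in both, and this share lay between 3.98% on chromosome III and 5.68% on chromosome V, with 5.18% on X.

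Most regions found in replicate 1 were found again in replicate 2, and the reverse held less often. Of the replicate 1 peaks, 3852 of 4343 (88.7%) overlapped a replicate 2 peak by at least 1 bp, while 3427 of 5585 replicate 2 peaks (61.4%) overlapped a replicate 1 peak. Random circular shifts of the other list within its chromosomes gave 32.7% ± 0.95 and 25.3% ± 0.70 (mean ± SD over 1000 shifts), so that the overlap was 2.71 and 2.43 times the shifted value. No shift reached the observed share (one-sided permutation p = 0.001 for each list, the smallest that 1000 shifts can give). The bases covered in both lists came to 12.1 Mb, which was 85.9% of the covered bases of replicate 1 and 63.2% of those of replicate 2.

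Peaks with higher scores, which were also wider, had a counterpart more often, and the share for shifted lists was higher for them too. Of the 1086 highest-scoring replicate 1 peaks (median width 5400 bp) 96.4% had a counterpart, against 40.4% for shifted lists, and of the 1085 lowest-scoring (1197 bp) 76.8% had one, against 27%. Of the 1397 highest-scoring replicate 2 peaks (5679 bp) 96.1% had one, against 32.6% for shifted lists. Of the 1396 lowest-scoring (1200.5 bp) 24.4% had one, against 20.3% for shifted lists (highest shift 24.5%, one-sided permutation p = 0.002). Score and width were not separated. Peaks found in replicate 2 alone had a median score of 183, and those with a counterpart a median of 1405. In replicate 1 the 491 peaks without a counterpart had a median score of 97.1, against 259 for the others.

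Some regions were strong in one replicate and absent from the list of the other. In replicate 1 the strongest was on chromosome V from 17117381 to 17134049, a domain of 16669 bp that scored 3100. Whether its sequence is repeated in the genome, which would leave the placement of its reads uncertain, was not examined for this or the other regions named here, because no genome sequence was used. The next were on X from 15806958 to 15811592 (score 2559) and on chromosome I from 2167404 to 2171408 (score 2426), from 11745031 to 11747629 (score 2389) and from 5690988 to 5698419 (score 2244). In replicate 2 the strongest were on chromosome III from 3164327 to 3172158 (score 3183), on V from 9454736 to 9462161 (score 3157) and on III from 9009007 to 9011677 (score 3106). A further region on III from 61846 to 67564 and one on IV from 1106975 to 1111793 were among several tied at 3100. Each of these 10 regions met at least 1 peak of the series-wide list.

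Scores of the shared regions were correlated between the replicates. Across the 3852 shared regions, Spearman's rho was 0.59 (95% bootstrap interval over peaks 0.56 to 0.61) and Pearson's r of the log10 scores was 0.54 (0.52 to 0.56). Peaks are not independent replicates, and these values describe 2 libraries. Each region is a replicate 1 peak, and several of them can share a single replicate 2 peak. In 1350 regions the replicate 2 score was exactly 3100, although that list holds 1103 such peaks. The bootstrap took such repeats as separate, so its intervals are too narrow. The value moved with the regions taken: rho was 0.80 over the 2703 regions in which each peak covered at least 50% of the other, 0.40 over the 2462 regions below 3100 in both, a set chosen after the data were seen, and 0.22 over the 1926 higher-ranked regions. In replicate 2, 558 peaks overlapped 2 or more replicate 1 peaks, and in replicate 1, 234 peaks overlapped 2 or more replicate 2 peaks.

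**Figure D2:**
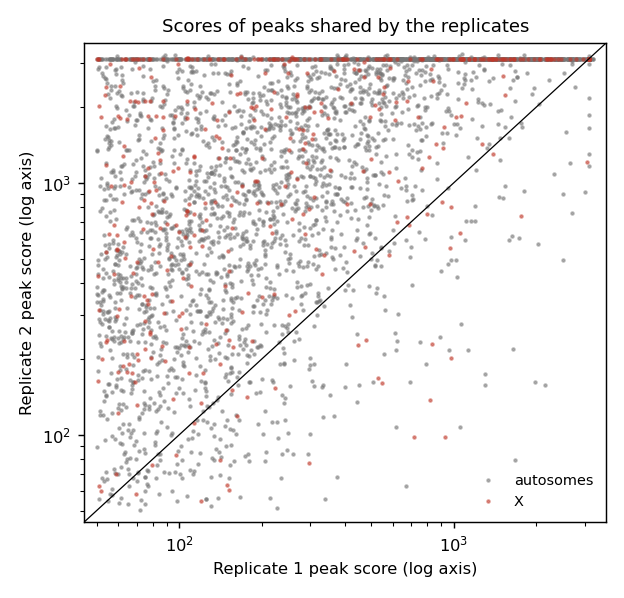
Peak scores of the 3852 regions shared by the replicates, replicate 1 on the x axis and replicate 2 on the y axis (both log axes, scores in the peak caller's units). Each point is a region, in red on X and in grey on the autosomes, and the line marks equal scores; the band at the top is the value 3100, and rho over all points was 0.59.

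The series-wide list held more and shorter peaks than the replicate lists. It held 18440 peaks, 18427 of them on the nuclear chromosomes, with a median width of 363 bp, and these covered 13.3 Mb, or 13.2% of the genome. Nearly every replicate peak met it: 4322 of 4343 in replicate 1 (99.5%, exact 95% binomial interval 99.3 to 99.7%) and 5285 of 5585 in replicate 2 (94.6%, 94.0 to 95.2%). These intervals cover counting error only. Random shifts of the series-wide list gave 35.6% ± 0.97 and 35.6% ± 0.80 (mean ± SD over 1000 shifts), and none reached the observed shares (one-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). The series holds no other precipitated samples, and the series-wide list carries the title of the series. The lists are therefore not independent of each other, and this overlap is no separate evidence for the replicate peaks. How the series-wide list was made is not stated in the sources used here. A replicate 1 peak met 2.43 series-wide peaks on average (median 2, highest 18), and a replicate 2 peak met 2.5 (median 2, highest 24). For domains wider than 10 kb the median was 5 in replicate 1 and 7 in replicate 2. With a stricter rule, by which a single series-wide peak must cover 50% of the replicate peak, 46.3% of replicate 1 peaks and 22% of replicate 2 peaks were matched.

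Of the nuclear peaks of the series-wide list, 8950 (48.6%) met both replicate lists, 1498 (8.13%) met replicate 1 alone, 4961 (26.9%) met replicate 2 alone, and 3018 (16%) met neither. The median score was 9.38 for peaks met in both and 4.29 for those in neither, and these scores were compared only within that list. Median widths were 614 bp and 224 bp. Not all peaks met in neither list were weak or narrow. At the right end of chromosome I, 1 ran from 15060208 to 15071393 (11186 bp, score 76.84) and another from 15071608 to 15072458 (score 52.21). The last peak there ended at 15054339 in replicate 1 and at 15054484 in replicate 2. These peaks were not named by the rule fixed in advance. Whether the sequence there is repeated in the genome, which would leave the placement of reads uncertain, was not examined.

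Chromosomes I and III were the richest in polymerase peaks, and V and X the poorest. In replicate 1 there were 61.4 peaks per Mb on I, 59.9 on III, 49.0 on II, 42.0 on IV, 29.1 on V and 28.2 on X. In replicate 2 there were 73.8 on I, 73.7 on III, 61.4 on II, 55.2 on IV, 36.9 on V and 44.1 on X. The share of bases under peaks gave a like picture, from 20.2% on I to 9.07% on X in replicate 1 and from 26.2% on III to 12.8% on V in replicate 2. Median peak widths differed less, between 2023 bp on IV and 2257 bp on II in replicate 1.

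**Figure D3:**
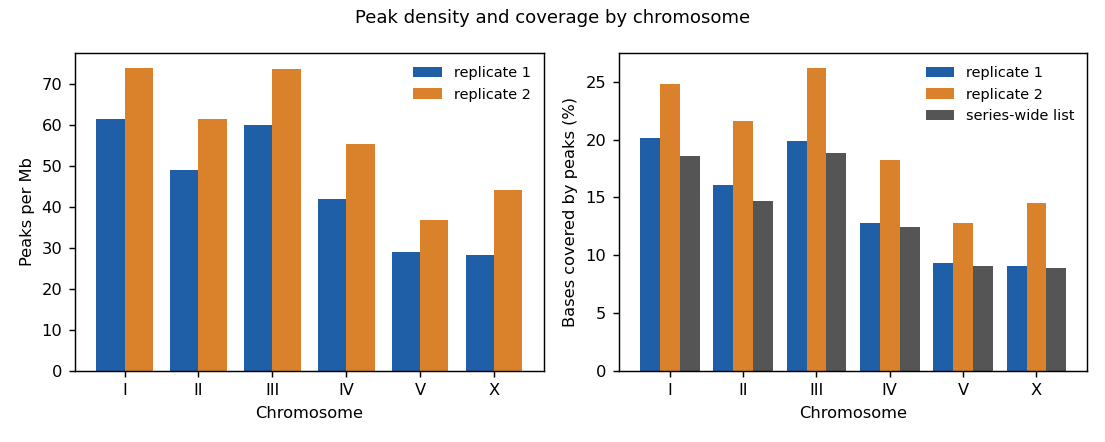
Peaks per Mb (left; replicates 1 and 2) and percentage of bases covered by peaks (right; both replicates and the series-wide list) on the 6 nuclear chromosomes; each bar is the value of one list. Chromosomes I and III carry the highest values in each list, and V or X the lowest.

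The X chromosome, which is subject to dosage compensation in hermaphrodites of this species, carried fewer peaks per Mb than the autosomes together. Over regions found in both replicates there were 25.1 per Mb on X and 41.3 per Mb on autosomes, a ratio of 0.61 (log2 ratio -0.72). Permuting the labels of the 18 X bins and 85 autosomal bins of 1 Mb gave a two-sided p of 1e-05, the smallest that 100000 resamples can give. The ratio was 0.61 in replicate 1 (permutation p = 1e-05), 0.76 in replicate 2 (p = 0.0026) and 0.68 in the series-wide list (p = 0.00024), and each of these 4 ratios stayed past the threshold of 0.05 after Benjamini-Hochberg adjustment over the 4 lists. X was not set apart from chromosome V, which had 25.2 shared regions per Mb: the ratio of X to V was 0.99 (permutation p = 0.95). In replicate 2 the ratio of X to V was 1.19 (permutation p = 0.045, or 0.18 after Benjamini-Hochberg adjustment over the 4 lists), a difference that did not hold up. Against chromosomes I to IV the ratio was 0.54 (permutation p = 1e-05). The comparison with V and that with I to IV were chosen after the data were seen. Bins are stretches of the genome and not biological replicates, and densities were not adjusted for the number of genes.

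Replicate 2 peaks on X had a replicate 1 counterpart in a smaller share of cases than those on the autosomes. On X, 376 of 781 replicate 2 peaks (48.1%, exact 95% interval 44.6 to 51.7%) had a replicate 1 counterpart, against 61.7% on V (58.1 to 65.1%) and 62.6 to 65.2% on the other autosomes. Replicate 2 peaks on X also had the lowest median score, 427 against 543 on III to 637 on V, and lower-scoring peaks had a counterpart less often on the whole. The shares by chromosome were not adjusted for score, and no shifted value was computed for single chromosomes. Peaks found in replicate 2 alone were on X in 18.8% of cases (17.1 to 20.5%), and those with a counterpart in 11% (9.94 to 12.1%). In replicate 1, X took 11.4% of the unmatched and 11.5% of the matched peaks.

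Within chromosomes, no common difference between the central 50% and the outer parts was found. Over regions found in both replicates, the centre was denser on 5 of 6 chromosomes, with a mean log2 ratio of 0.12 ± 0.29 (SD, n = 6 chromosomes; two-sided exact sign-flip permutation p = 0.41, where the smallest possible is 0.03). Chromosome V showed the widest contrast, with 30.2 regions per Mb in its centre and 21.8 and 18.7 in its left and right outer parts. X showed the opposite order, with 22.3 in the centre and 27.5 and 28 in the outer parts. On chromosome IV the left part had 44.4 regions per Mb and the right part 30.6, while on III the left had 40.9 and the right 59.2. The sign of the mean differed between the replicates: the mean log2 ratio was -0.05 ± 0.23 in replicate 1 (2 of 6 chromosomes denser in the centre, exact p = 0.59) and 0.26 ± 0.27 in replicate 2 (5 of 6, exact p = 0.06), and none of the 4 lists passed the threshold of 0.05. The difference between the replicates was not tested.

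**Figure D4:**
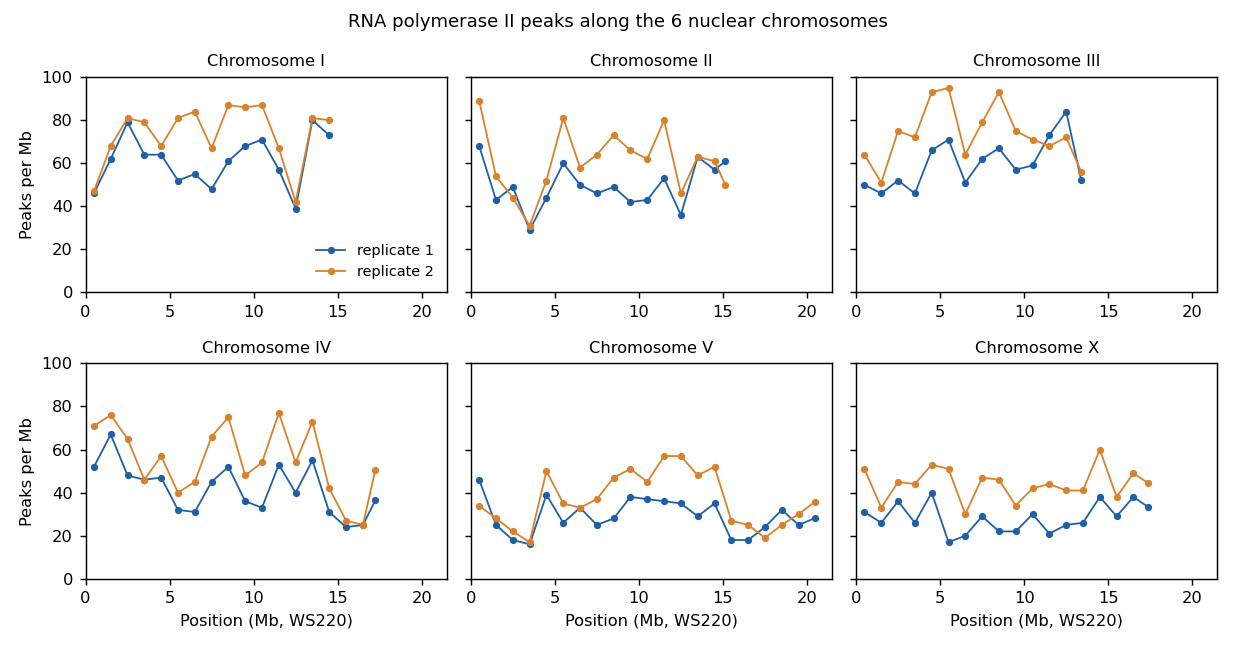
Peaks per Mb (y axis) in successive 1 Mb bins along each nuclear chromosome (x axis, position in Mb, WS220), for replicate 1 and replicate 2; each point is one bin, and bins shorter than 0.25 Mb at chromosome ends are not drawn. On X the mean was 28.2 peaks per Mb in replicate 1 and 44.1 in replicate 2, and on V 29.1 and 36.9.

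The densest and the emptiest megabases lay on different chromosomes. Among complete 1 Mb bins, the 6 with most shared regions were on III (5 to 6 Mb and 12 to 13 Mb, 68 regions each; 8 to 9 Mb, 67; 4 to 5 Mb, 65) and on I (9 to 10 Mb and 13 to 14 Mb, 65 each). The 6 with fewest were on V (17 to 18 Mb, 12 regions; 2 to 3, 3 to 4 and 15 to 16 Mb, 14 each) and on X (9 to 10 Mb, 13; 5 to 6 Mb, 16). Shared regions covered 27.1% of the bin at 4 to 5 Mb on III and 2.22% of the bin at 17 to 18 Mb on V.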

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

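The test of list length was set out before its result was seen, and the other tests of this part after.

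The series-wide list held 13 peaks on the mitochondrial genome, between positions 146 and 12737, where neither replicate list had a peak, and a peak at the first base of 6 of 6 nuclear chromosomes, where replicate 1 had one within the first 10 bp of 3 (I, II and X) and replicate 2 of 0; the mitochondrial peaks stood out as signal outside the nuclear comparisons, from DNA that RNA polymerase II does not transcribe. Chance placement is argued against for the chromosome starts, since random shifts covered at most 4 first bases (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). A lower threshold of the series-wide list was tested as the whole explanation of the mitochondrial peaks. Their median score was 6.99, above the 3.26 to 5.97 for medians of as many nuclear peaks drawn from those met in neither replicate list (the central 95% of 10000 draws). The 13 peaks lie close together on a single small genome, while the draws took separate nuclear peaks. That range may therefore be too narrow for them, and the test cannot decide. A lower threshold also stays open for the starts of III, IV and V, which met neither replicate list and scored 3.33, 12.21 and 10.15. For both kinds of peak the handling of reads from multi-copy or repeated DNA, or its scaling against input, is an untested candidate explanation. No biological explanation was tested.

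X took 11.5% of the peaks of replicate 1 and 14.0% of those of replicate 2, a ratio of 1.21 (95% interval 1.12 to 1.34 from resampled 1 Mb bins). The larger number of peaks in replicate 2 is argued against as the whole explanation. With replicate 2 limited to its 4343 strongest peaks X still took 13.7%, a ratio of 1.19 with a lower bound of 1.08. That cut removed only the lowest-scoring peaks, so it cannot decide on the lower-scoring peaks that remained. Peaks found in replicate 2 alone had a median score of 183 and were on X in 18.8% of cases. For replicate 2 peaks with a counterpart these values were 1405 and 11%. Autosomal neighbours joined into fewer peaks in replicate 2 are argued against as well, since X took 11.4% and 13.5% of the covered bases, a ratio of 1.18 with a lower bound of 1.098. The interval covers the spread over bins of 1 sample against 1 other, so a difference between these libraries in enrichment, depth or embryo stage stays open and untested. No biological explanation was tested.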

How the results depend on the processing

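The overlap of the replicates stayed above random shifts (permutation p = 0.001) under all 5 alternatives in both directions, between 62.2% and 89.1% for replicate 1 and between 48.4% and 72.3% for replicate 2; the lowest share in each came with an overlap of 50% of both peaks. Spearman's rho of the scores moved from 0.59 to 0.80 with an overlap of 50% of both peaks, to 0.22 in the stronger part of the shared peaks, and to 0.40 in peaks below 3100, an alternative chosen after seeing the data; the cause was not tested, although a ceiling limits what ranks at the top can show. The share of replicate peaks met by the series-wide list fell to 46.3% (replicate 1) and 22% (replicate 2) when 50% of the replicate peak had to be covered by a single peak, and to 91.3% and 78.5% with the stronger part of that list, which has fewer peaks by construction. The log2 ratio of X to autosomes kept its sign and stayed past the threshold in 7 of 8 alternatives (-0.40 with replicate 2 alone, -0.72 with replicate 1 alone, -0.89 in the stronger part of each list). Among these 7, bins of 500 kb cannot change the ratio itself, only its p. Another, against chromosomes I to IV (-0.90), was chosen after seeing the data and leaves out V, the autosome with the lowest density. Against chromosome V alone, also chosen after seeing the data, the log2 ratio was -0.010 (permutation p = 0.95). The centre against the outer parts passed in no alternative, and its mean log2 ratio turned negative in replicate 1 alone (-0.0454, against 0.256 in replicate 2 alone) and in the series-wide list (-0.0481); the cause was not tested. Over the 5 autosomes only, added after seeing the data, it was 0.21 (exact permutation p = 0.06, the smallest that 5 chromosomes allow). No paired analysis was possible because the input samples, which share replicate numbers with the precipitated ones, have no peak list used here. The other settings of the gene-based comparisons were not run, since no positions were carried between builds. Depth is unknown, so its effect on the number of weak peaks was not assessed.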

Other observations

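The test of random spacing was set out before its result was seen. Long stretches without a polymerase peak in either replicate were concentrated on chromosome V. Stretches longer than 100 kb numbered 82, of which 30 were on V, 16 on X, 15 on IV, 8 each on I and II, and 5 on III. They made up 23.1% of V, 12% of X, 11.4% of IV and 5.15 to 6.72% of the other 3 chromosomes. On each autosome most lay in the outer parts of the chromosome, outside the central 50%: 6 of 8 on I, 6 of 8 on II, 5 of 5 on III, 12 of 15 on IV and 23 of 30 on V. On X 6 of 16 did. The longest was on X from 1543142 to 1845576 (302 kb), and the next 9 were all on V, among them 364613 to 639885 (275 kb) and 18321128 to 18594330 (273 kb). The first of these 2 held no peak of the series-wide list either. These stretches were picked for their length after the values were seen.

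The hypothesis that such stretches are what random spacing gives was tested. With the same domains placed at random within their chromosomes 1000 times, the longest stretch had a median of 159 kb and a 95th percentile of 214 kb, against 302 kb observed, and stretches over 100 kb numbered 13 on average and at most 24, against 82. Random spacing is thus argued against. Clustering of expressed genes could give such spacing, as could repeated sequence to which reads cannot be placed; neither was tested.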
